A study of Mus musculus with 8 samples.

How the data were processed

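Single-cell RNA was measured in kidney and bone marrow of MRL/lpr mice (LPR) and MRL/MPJ mice (MPJ) with 10x Genomics droplet libraries that tag the 3' end of each transcript. Per the labels' protocols, kidneys were minced and digested with collagenase D on a tissue dissociator, bone marrow cells were collected by centrifugation without such a digestion, and red cells were lysed in both tissues. The labels name no cell sort, while the series design names lineage-negative CD45+ Sca1+ cells of the kidney, so whether any library was enriched before loading was not given in the sources used here. Each library was deposited as UMI counts per gene and cell barcode, and per the file headers these counts came from Cell Ranger 6.1.1. The submitters' processing notes name the mm10 genome, Cell Ranger, Seurat 4.4.0 and R, without saying what each was used for. The annotation release and the way cells were called were not given in the sources used here. Because the lowest total per barcode differed between libraries, from 503 to 3343 UMIs, shares of cells were also computed above an equal floor of 3343 UMIs.

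Barcodes were kept with at least 500 UMIs, at least 300 detected genes and at most 20% mitochondrial counts. A stricter alternative used 1000 UMIs and 10%. Doublets were scored per library with Scrublet in scanpy 1.11.5 at an expected rate of 8%. Its automatic threshold marked under 0.5% or over 25% of cells in LPR kidney replicates 2, 3 and 4 and in the MPJ kidney library, so there the 6% of cells with the highest scores were removed instead. The removed share was 4.28% and 2.66% in the LPR marrow libraries, 2.81% in MPJ marrow, 1.78% to 6.21% in LPR kidney and 6.94% in MPJ kidney. No correction for free RNA was applied. Its traces were followed with fixed lists of tubule, neutrophil granule and haemoglobin genes.

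Cells of all 8 libraries were clustered together on 2000 variable genes, 40 principal components and 15 neighbours, with Leiden clustering at a resolution of 1.5 and 3.0 as the finer alternative. Clusters were called X-like from cell type markers fixed before the data were examined. The thresholds for naming were set after the clusters had been seen: a marker score of at least 1.0 and at least 3 markers detected in 20% of the cluster's cells. Where more than 1 list passed, the name went to the list with most markers among the cluster's 10 leading genes, and then to the highest score. A cluster stayed unnamed despite passing if another list had more markers among those 10 genes. That left out 1 cluster of 552 cells led by haemoglobin genes and 1 of 83 cells led by Fcgr4 and Gngt2 (scores 2.00 and 1.29), and with finer clusters further ones, of 294 cells led by Tm4sf1, 634 led by Retnla, 2350 led by Icos and 80 led by Prtn3. Clusters that stayed unnamed held 212, 318, 791 and 458 cells of LPR kidney replicates 1 to 4, 33 of MPJ kidney, 460 and 275 of the LPR marrow libraries and 513 of MPJ marrow. Clusters with strong markers of more than 1 class were set aside as mixed.

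Shares of cells were compared between 5 kidney and 3 marrow libraries with exact 2-sided permutation tests, with Benjamini-Hochberg adjustment over 21 classes, and again between the 4 LPR kidney and 2 LPR marrow libraries. Intervals on the share of a single library are exact Clopper-Pearson intervals at 95% and cover counting error only. A transcript gate selected cells with at least 1 UMI of Ptprc and of Ly6a and none of 15 lineage genes, after each cell had been thinned to 2000 UMIs. A myeloid marker score was planned as a position between progenitors and monocytes. It was the mean log level of myeloid progenitor and monocyte markers minus that of HSPC markers in each thinned cell. Levels were counts scaled to the cell's total, not CPM, with 1 added before the natural log. The score was taken as the median per library and class. Myeloid progenitors score highest on it, so it does not order them before monocytes.

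For expression, counts were summed per library and class where a class held at least 20 cells (50 as an alternative). They were tested with edgeR 4.0.16 in R 4.3.3, by robust quasi-likelihood fits with TMM scaling, edgeR's filter on low counts and Benjamini-Hochberg adjustment at 0.05. All libraries with enough cells of the class entered 1 fit with a mean per group, so the groups shared an estimate of the spread, to which groups of 1 library add nothing. Comparisons with an MPJ group therefore assume that its lone library varies like the others. Levels are given as CPM, counts scaled to the class's UMI total in each library, as mean ± SD over libraries, and errors on log2 fold changes are standard errors. DESeq2 1.42.0, relative log expression (RLE) scaling, no filter on low counts, retained doublets, finer clusters, the 3 LPR kidney libraries of one numbered title set summed as a single sample, the title set as a block, and each library left out in turn were the alternatives. Camera in limma 3.58.1 tested 20 fixed gene lists with a preset inter-gene correlation of 0.01, and again with an estimated correlation. The lists covered the stem cell program, myeloid, lymphoid and erythroid or megakaryocyte priming, type I interferon and interferon gamma responses, MHC class II, S phase, G2M phase, NF-kB targets, immediate early genes, hypoxia and glycolysis, homing and adhesion, endosomal Toll-like receptors, complement and efferocytosis, lipid-associated or scar macrophages, and T cell exhaustion and effector genes. Background lists of neutrophil granule, haemoglobin and tubule genes completed the set.

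The genes named were the 12 largest changes in each direction past an adjusted p of 0.05 with at least 50 CPM in the higher group. They also had to have every library of one group above every library of the other, keep the direction when the summed libraries replaced their parts, and reach in the class at least 0.25 of their level over all cells. Up to 4 members of each list, the cell type markers, Fas and Ly6a were added. Xist, Y-linked genes, predicted genes and receptor segments were left out. Where a group held 0 counts, the fold is given as a lower bound against 3 counts over the group. Where it held 1 to 3 counts, a ratio with a counting interval is given. Counts cover sampling error only, since UMIs reduce but do not remove amplification effects.

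The count models were tested on simulated data with 200 changed genes per draw. For monocyte-like cells between tissues, 55.6% of genes changed 2-fold and 87.6% of those changed 4-fold were recovered, with 13.4% false calls. The corresponding values were 9.2%, 65.8% and 11.6% for neutrophil-like cells between tissues. They were 19.6%, 64.8% and 7.66% for progenitor-like cells between strains in marrow, 18.6%, 75.2% and 14.1% for marrow monocyte-like cells between strains, and 0%, 0.4% and 0% for kidney macrophage-like cells between strains. The false share lay above the nominal 5% in all of these except the last, so lists of single genes hold more false calls than their adjusted p states. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.

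Coordinates are those of GRCm38/mm10 with the GENCODE vM21 annotation. The grouping, the tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. A further 5 alternatives were chosen after seeing the data: the patrolling-type monocyte cluster alone, the other classes between tissues, the other classes between strains in kidney, an equal UMI floor for shares, and the gate without haemoglobin genes. The planned tests of kidney progenitor-like classes against marrow, and of monocyte-like and T-like cells between strains in kidney, could not be fitted because 1 side held 0 or fewer than 20 cells. Barcodes removed by the filters were not searched for progenitors. The TLR7 agonist model and the cell transfer that the series design names were not analysed here.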

Results

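Kidney and bone marrow cells were profiled by droplet single-cell RNA sequencing in MRL/lpr mice (LPR), which carry a Fas mutation and develop lupus nephritis, and in MRL/MPJ mice (MPJ), the parental strain with intact Fas. The 8 libraries formed 4 groups: LPR kidney with 4 libraries, LPR bone marrow with 2, and MPJ kidney and MPJ bone marrow with 1 each. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. LPR kidney replicates 1 to 4 held 78434805, 86458768, 89819882 and 108922168 UMIs, the LPR marrow libraries 88894500 and 111702398, MPJ kidney 43947601 and MPJ marrow 76255086. After filtering, 7408, 8864, 8880 and 9907 cells remained in LPR kidney, 7530 and 10642 in LPR marrow, 2106 in MPJ kidney and 5979 in MPJ marrow, with median depths of 4310 to 6879 UMIs. In the MPJ kidney library 76.9% of barcodes exceeded 20% mitochondrial counts, against 3.4% to 22.3% in LPR kidney, and its kept cells had a median of 14.6% against 2.02% to 6.17%. Counts of libraries of the same group differed by more than sampling noise (chi-square per degree of freedom 235 to 1081), which argues against one library deposited more than once, and none were merged. Such a difference does not show separate animals or preparations, since UMIs cluster within cells and the makeup of cells differed between libraries.

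Fas (ENSMUSG00000024778, chromosome 19, 34290666 to 34327772 on the plus strand, GRCm38/mm10), the death receptor mutated in lpr mice, reached 4.71, 6.16, 7.79 and 7.13 CPM over all cells of LPR kidney replicates 1 to 4. It reached 6.29 CPM in MPJ kidney, 3.98 and 8.62 CPM in LPR marrow and 4.77 CPM in MPJ marrow. The lpr mutation is an insertion inside the gene, and a 3' tag does not show whether a transcript is intact, so these levels do not check the strain labels.

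The first comparison asked which cells each tissue held. Macrophage-like cells, in 5 clusters of which 1 was led by the complement genes C1qa and C1qc and another by Gpnmb and Mmp12, made up 22.5% ± 11.1 (SD, n = 4) of LPR kidney cells and 0.148% ± 0.00302 (SD, n = 2) of LPR marrow cells. Neutrophil-like cells made up 0.844% ± 0.806 of LPR kidney and 24.0% ± 12.8 of LPR marrow, and monocyte-like cells 5.74% ± 2.46 and 13.3% ± 2.07. Neutrophil-precursor-like cells, the stage that makes granule proteins, were 0.0208% of kidney and 21.4% ± 0.654 of marrow cells, and erythroid-like cells 0.0352% and 12.8% ± 6.92. T-like cells made up 27.4% ± 11.3 of LPR kidney cells and 5.63% ± 4.51 of LPR marrow cells. In exact 2-sided permutation tests of all 5 kidney against all 3 marrow libraries, the macrophage-, neutrophil-, monocyte-, neutrophil-precursor- and erythroid-like shares each gave p = 0.0357, the smallest value this design can give (adjusted p = 0.0441 over 21 classes). The T-like share gave p = 0.143 (adjusted p = 0.15) in the same exact permutation test. With LPR libraries alone, 4 against 2, the smallest p that the exact permutation test can give is 0.133. As a share of blood and immune classes alone, the monocyte-like difference between the LPR means, kidney minus marrow, was -3.15 percentage points rather than -7.54 (exact permutation p = 0.429 over all libraries). Under the stricter cell filter the macrophage-like difference was 24.4 points rather than 22.3 (exact permutation p = 0.143). Only kidney was digested, tubule-like cells took 7.65% to 60.0% of LPR kidney libraries, and the lowest UMI total per barcode differed between libraries (503 to 3343). Whether kidney cells were enriched before loading is not stated in the labels. Those factors can set shares. Above an equal floor of 3343 UMIs, an alternative chosen after seeing the data, T-like cells made up 10.2% of LPR kidney and 3.56% of LPR marrow (exact permutation p = 0.179). Neutrophil-like cells then made up 0.284% and 16.9%, and macrophage-like cells 33.0% and 0.164%, each with an exact permutation p of 0.0357.

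**Figure D1:**
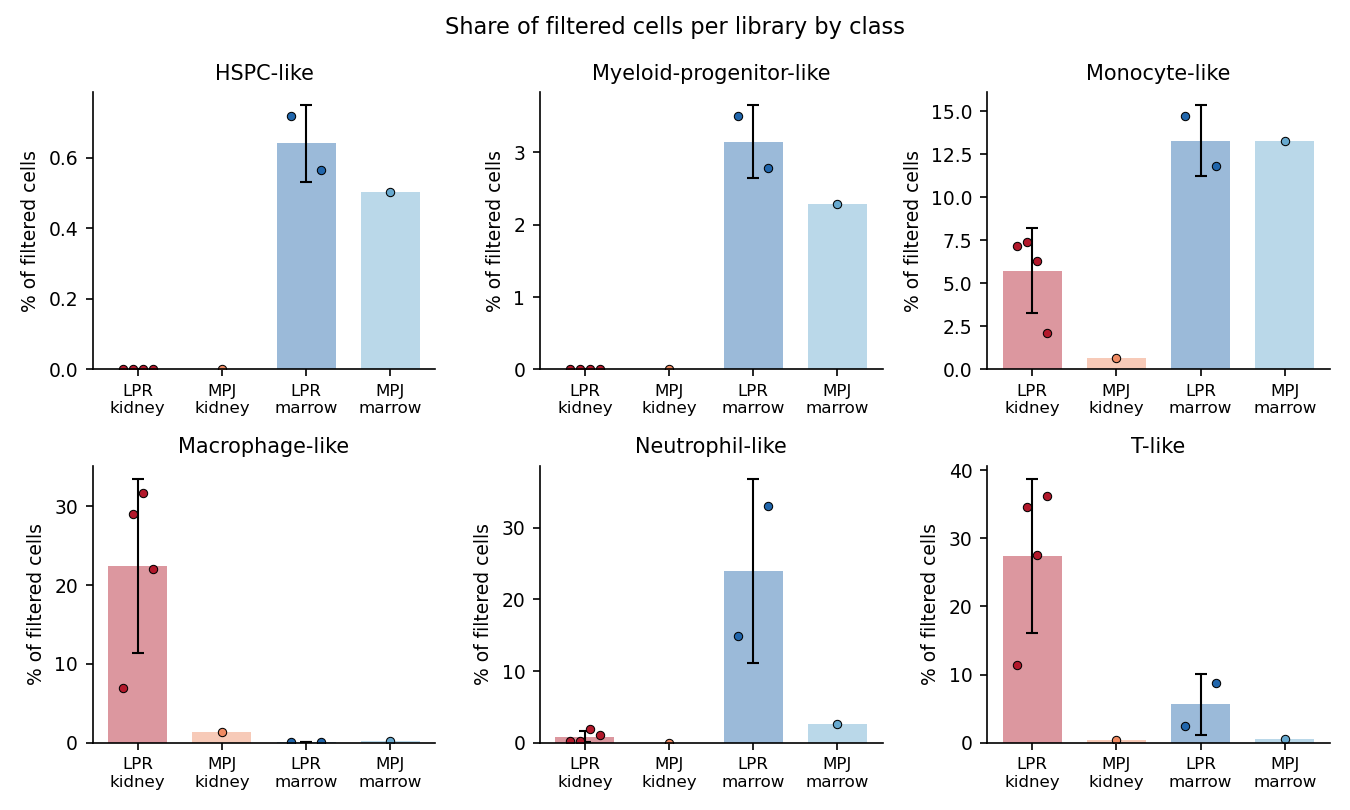
Each panel gives the share of filtered cells (y axis, %) of one class in LPR kidney, MPJ kidney, LPR marrow and MPJ marrow, with bars for means, points for libraries and error bars for the SD in the LPR groups. Progenitor-like classes are at 0 in the kidney groups, macrophage-like cells average 22.5% in LPR kidney, and neutrophil-like cells average 24.0% in LPR marrow.

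Between strains, macrophage-like cells were 1.42% of MPJ kidney cells (30 of 2106, exact 95% interval 0.963% to 2.03%) against 7.01% to 31.7% in the LPR kidney libraries. T-like cells were 0.427% of MPJ kidney (9 of 2106, interval 0.196% to 0.81%) against 11.4% to 36.2%, and monocyte-like cells 0.665% (interval 0.364% to 1.11%) against 2.11% to 7.38%. Tubule-like cells made up 85.6% of MPJ kidney. Among the 182 MPJ kidney cells of blood and immune classes, macrophage-like cells were 16.5% (interval 11.4% to 22.7%) against 21.5% to 43.0% in LPR kidney libraries, and T-like cells 4.95% (interval 2.29% to 9.18%) against 35.0% to 56.3%. On that denominator monocyte-like cells were 7.69% in MPJ kidney (interval 4.27% to 12.6%), within the 3.28% to 22.1% of the LPR kidney libraries. In marrow, erythroid-like cells were 33.4% of MPJ cells (interval 32.2% to 34.6%) against a mean of 12.8% in LPR, and neutrophil-like cells 2.64% (interval 2.25% to 3.08%) against 24.0%. Filtering removed 3841 barcodes with few genes and more than 50% haemoglobin counts from MPJ marrow, and 2116 and 93 from the LPR marrow libraries. The lowest UMI total per barcode was 3343 in MPJ marrow, but 2315 and 509 in the LPR marrow libraries. Neutrophil-like clusters had median depths of 1818, 3091 and 4300 UMIs, so shallow cells of this class were absent from MPJ marrow alone. Above the equal floor the LPR marrow mean was below 24.0%, as given before. In kidney the lowest total was 2184 in MPJ and 503 to 2356 in LPR libraries. These strain differences in share were not tested, since each MPJ group held 1 library, and the intervals cover counting error only.

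The series design names stem and progenitor cells of the kidney, so haematopoietic stem and progenitor cells (HSPC) were sought there. HSPC-like clusters, marked by Cd34, Meis1 and Flt3, and myeloid-progenitor-like clusters, marked by Mpo and Elane, held 0 of 35059 LPR kidney cells. Both were named by thresholds set after the clusters had been seen. Counting error alone allows a share of cells so named of up to 0.00856%. A further cluster that scored highest on myeloid progenitor markers was named monocyte-like and held 1 cell each of LPR kidney replicates 2 and 3. A basophil- or mast-like cluster with a myeloid progenitor score of 1.79 held 1 cell each of LPR kidney replicates 1, 2 and 3. An unnamed cluster led by Car1 held 1 cell each of LPR kidney replicates 1 and 3. The HSPC-like and myeloid-progenitor-like clusters held 0 of 2106 MPJ kidney cells, where counting error alone allows up to 0.175%. Most of those cells were tubule-like. Among the 182 MPJ kidney cells of blood and immune classes the bound was 2.01%. In MPJ marrow both progenitor-like classes together made up 3.06% of blood and immune classes. These bounds do not cover progenitors that the clustering or the naming missed. In LPR marrow the same classes made up 0.640% ± 0.108 (SD, n = 2, 114 cells) and 3.15% ± 0.506 (561 cells), and in MPJ marrow 0.502% (30 cells, interval 0.339% to 0.716%) and 2.29% (137 cells, interval 1.93% to 2.70%). For each class the exact 2-sided permutation test of 5 kidney against 3 marrow libraries gave p = 0.0357 (adjusted p = 0.0441), the smallest it can give. Single kidney cells were searched for at least 4 HSPC markers together with a Ptprc UMI. This HSPC marker search found 3 cells, all in LPR kidney replicate 3 and in neutrophil-, endothelial- and distal-tubule-like clusters. A like search for granule progenitor markers, also with a Ptprc UMI, found 0 kidney cells. Kidney cells without a Ptprc UMI could not be found by either search. The HSPC marker search found only 5 of 54 and 9 of 60 of the HSPC-like cells of the LPR marrow libraries. It found 0 of 30 in MPJ marrow, so it misses most such cells. The granule search likewise found only 38 of 264 and 39 of 291 of the thinned myeloid-progenitor-like cells of the LPR marrow libraries. In MPJ marrow it found 16 of 137. Ptprc was detected in only 22.807% of thinned HSPC-like and 14.955% of thinned myeloid-progenitor-like cells of LPR marrow. At the thinned depth the Ptprc requirement alone therefore left out most such cells.

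Sca-1, encoded by Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031 on the minus strand), and CD45, encoded by Ptprc (chromosome 1, 138062861 to 138175708 on the minus strand), define with absent lineage markers the population that the series design names. A transcript gate on these genes, after thinning to 2000 UMIs, held 1.84% ± 0.630 (SD, n = 4) of LPR kidney cells and 0.278% ± 0.262 (SD, n = 2) of LPR marrow cells. It held 0.427% of MPJ kidney (9 of 2106, interval 0.196% to 0.81%) and 0 of 5979 MPJ marrow cells (interval up to 0.0617%). Macrophage-like cells made up 54.7% ± 13.2 of the gate in LPR kidney (347 of 597 cells, 35.2% in the lowest library) and monocyte-like cells 14.2% ± 13.5. The macrophage-like part was 38.5% ± 9.40 unthinned (290 of 736 cells), with 86 distal-tubule-like and 74 proximal-tubule-like cells, and 47.2% ± 10.1 at 2 or more Ly6a UMIs (126 of 255 cells). No kidney cell was HSPC-like before the gate, so its makeup says nothing further about that class. In LPR marrow plasmacytoid-dendritic-like cells made up 55.2% ± 2.69 of the gate (28 of 52 cells), and the gate caught 1 of 114 HSPC-like cells. The LPR means differed by 1.56 percentage points, and all kidney against all marrow libraries gave an exact 2-sided permutation p of 0.0714. The difference was 1.72 points under the stricter cell filter, 1.74 with doublets kept and 1.94 unthinned, each at an exact permutation p of 0.0357. In thinned LPR kidney cells Ly6a was detected in 95% of endothelial-like, 19.5% of macrophage-like (median depth 9140 UMIs) and 6.51% of NK-like cells (median depth 3108.5 UMIs). Of these thinned cells the gate held 4.36% of 7955 macrophage-like, 3.48% of 1895 monocyte-like and 0.387% of 7743 T-like cells. It held 5.41% of 370 dendritic-like and 25.6% of 43 plasmacytoid-dendritic-like cells. Thinning left out 381, 599 and 2132 cells of LPR kidney replicates 2 to 4 and 923 of LPR marrow replicate 2. Of thinned HSPC-like cells of LPR marrow, 16.7% carried a Ly6a UMI (median depth before thinning 14814 UMIs). With haemoglobin genes dropped from the lineage genes, an alternative chosen after seeing the data, the gate held 0.748% rather than 0.278% of LPR marrow cells, 13 rather than 0 MPJ marrow cells, and 4 rather than 1 of the 114 HSPC-like cells of LPR marrow.

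**Figure D2:**
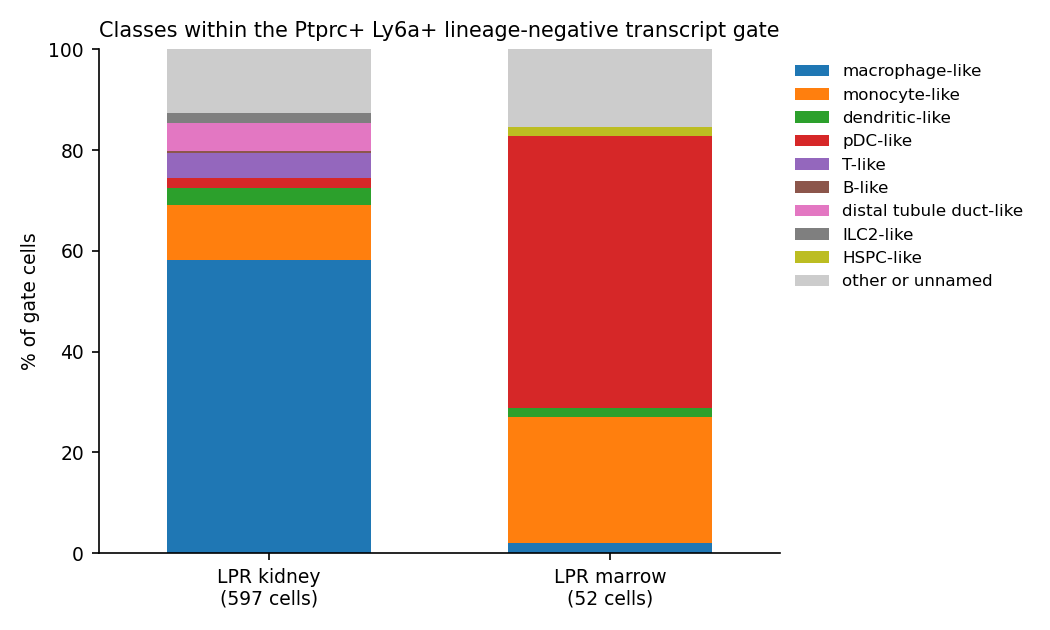
Stacked bars give the class makeup (y axis, % of gate cells) of cells with Ptprc and Ly6a but no lineage transcripts, pooled over libraries and thinned to 2000 UMIs, for 597 LPR kidney cells and 52 LPR marrow cells. Colours stand for classes; 347 of the kidney cells are macrophage-like and 28 of the marrow cells plasmacytoid-dendritic-like.

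The series design also names a path from marrow to kidney, and cells were scored by their myeloid progenitor and monocyte markers minus their HSPC markers. Myeloid progenitor markers count toward the high end, so the score does not order progenitors before monocytes. Marrow myeloid-progenitor-like cells had library medians of 1.19 to 1.21 and marrow HSPC-like cells of -0.181 to -0.0304. Monocyte-like cells had a mean of library medians of 0.838 ± 0.0175 (SD, n = 2) in LPR marrow, 0.788 in MPJ marrow and 0.562 ± 0.0459 (SD, n = 4) in LPR kidney. The LPR means differed by -0.276, kidney minus marrow. Kidney cells lay mostly in a cluster marked by Fcgr4, and marrow cells mostly in others, of which the one marked by F13a1 and Fn1 scored highest on the myeloid progenitor markers that the score counts upward. The exact 2-sided permutation p was 0.0571 for the 4 LPR kidney against all 3 marrow libraries and 0.133 for 4 against 2 within LPR, each the smallest the test can give. Unthinned, the difference was -0.347.

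Monocyte-like cells of LPR kidney were then compared with those of LPR marrow. Among 11566 genes, 3026 were higher and 3116 lower in kidney (edgeR, n = 4 and 2). Ptgs2 (chromosome 1, 150100031 to 150108227, plus strand), the inducible prostaglandin synthase, was at least 971-fold higher at 89.9 ± 38.3 CPM against 0 counts in marrow (edgeR adjusted p = 0.0017). The chemokines Ccl4 (log2 fold change 10.98 ± 0.59, 865 ± 367 CPM against 0.433) and Cxcl2 (9.86 ± 1.43, 1509 ± 916 CPM against 1.79), which attract monocytes or neutrophils, rose at edgeR adjusted p of 4.4e-06 and 0.005. Il10, an anti-inflammatory cytokine, was 2124-fold higher (counting interval 379.9 to 84010, from 1 marrow count). Acod1, which makes itaconate, rose by 8.25 ± 0.89, Marco, a scavenger receptor, by 7.39 ± 0.74, and Slc7a11, a cystine transporter, by 7.32 ± 0.45. Hcar2, Cd83 and Ccl3 rose by 8.83 ± 1.07, 7.76 ± 0.51 and 7.39 ± 0.44, as did the stress-linked Nr4a3 (7.98 ± 0.47) and Hspa1a (7.88 ± 1.09), which has a near-identical copy in Hspa1b. Cxcl2 and Acod1 were also leading genes of a neutrophil-like cluster of the kidney, and Hcar2 of a finer one. A finer cluster led by Cxcl2, Acod1 and Il1r2 was mixed between monocyte and neutrophil markers. It held 12, 22, 139 and 11 LPR kidney cells and 0 marrow cells, so neutrophil-like cells or their RNA may enter these rises.

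The largest falls in kidney monocyte-like cells included Elane and Mpo. Elane (chromosome 10, 79886247 to 79888215, plus strand), neutrophil elastase, was at least 2217-fold lower at 0 counts against 611 ± 15.6 CPM (edgeR adjusted p = 2.8e-08). Mpo (chromosome 11, 87793581 to 87804413, plus strand), myeloperoxidase, was lower by a ratio of 7720 (counting interval 1385 to 304930). Ctsg and Prtn3, both serine proteases of primary granules, changed by -10.14 ± 0.38 and -9.25 ± 0.29 log2, and Ms4a3, expressed in granulocyte-monocyte progenitors, was at least 480-fold lower. Among genes of cell division, Plk1, a mitotic kinase, changed by -6.85 ± 0.30, Ube2c by -6.49, Ccna2, a cyclin, by -6.28 and Cenpf by -6.20. The fold change of Ly6a was 2.55 ± 0.50 (68.0 ± 36.3 against 12.7 ± 2.4 CPM, edgeR adjusted p = 0.0068), and that of Fas 0.53 ± 0.33 (edgeR adjusted p = 0.2). Over all cells Ly6a stood at 592 to 952 CPM in the LPR kidney libraries and at 71.7 and 108 CPM in LPR marrow. Free RNA may therefore enter the Ly6a rise. Monocyte-like cells of kidney lay mostly in a cluster marked by Fcgr4, Treml4 and Ace, genes of patrolling monocytes (524, 645, 556 and 209 cells). Marrow cells lay mostly in clusters marked by Vcan and Ccr2 (473 and 594 cells) or by F13a1 and Fn1 (510 and 428). The cluster marked by F13a1 and Fn1 scored highest on myeloid progenitor markers and entered the monocyte-like class at a score of 1.001, against a threshold of 1.0 set after the clusters had been seen. It held 2 kidney cells, and the falls named here compare classes of this unlike makeup. Without LPR marrow replicate 1 the number of changed genes was 3936 rather than 6142.

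By fixed lists, 22 of 22 NF-kB targets rose (median log2 fold change 4.65; Tnfaip3, a brake on NF-kB, by 5.04 ± 0.23 and Nfkbiz by 4.29), also when adjusted over the list alone. Of 18 immediate early genes 16 rose (17 adjusted over the list alone, median 3.03), among them Jund, a part of the AP-1 factor, by 2.89. Only kidney was digested, so for both lists handling and tissue biology cannot be told apart. Of the G2M phase list 51 of 52 fell (52 adjusted over the list alone, median -4.58; Aurkb by -5.55), and of the S phase list 40 of 42 (40 alone, median -2.87; Mcm5 by -3.29). Of 20 myeloid priming genes 6 rose and 10 fell (6 and 11 adjusted over the list alone, median -0.85). Homing genes rose in 13 and fell in 1 of 17 (Itgax by 4.51 ± 0.22, Itgal by 3.00 ± 0.17, both integrin chains). Complement and efferocytosis genes rose in 12 and fell in 3 of 16 (Cd36, a scavenger receptor, by 4.97 ± 0.25 and Cfb by 3.42 ± 0.21), and lipid-associated macrophage genes rose in 10 and fell in 2 of 15 (11 and 2 adjusted over the list alone; Mmp14, a matrix protease, by 6.01 ± 0.37, Fn1 by -3.54 ± 0.78). With the preset correlation, camera's adjusted p was 2e-17 for NF-kB targets, 9e-13 for immediate early genes and 5.4e-07 for myeloid priming, and each of these 3 held with an estimated correlation (adjusted p = 0.049). The other calls did not hold: S phase had a preset adjusted p of 2.8e-25 and an adjusted p = 0.144 with an estimated correlation. G2M phase (2.8e-54), homing (1.6e-06) and complement (8.3e-07) each had an adjusted p = 0.051 with an estimated correlation, and lipid-associated genes (0.00027) an adjusted p = 0.054 with an estimated correlation.

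Smaller calls were made for endosomal Toll-like receptor genes (8 of 14 rose, median 0.57; Tlr7, a sensor of single-stranded RNA, by 2.26 ± 0.18; camera adjusted p = 0.024, and adjusted p = 0.474 with an estimated correlation) and T cell exhaustion genes (3 rose and 1 fell of 9, 5 and 1 adjusted over the list alone; Havcr2, an inhibitory receptor, by 5.99 ± 0.20; camera adjusted p = 0.0093, and adjusted p = 0.265 with an estimated correlation). Markers of other cells moved with them: tubule genes rose in 9 of 12 (median 9.02, or 6.66 with genes at 0 counts at their bound; Umod, the main urinary protein of the tubule, at least 115-fold; camera adjusted p = 0.0013, and adjusted p = 0.418 with an estimated correlation). Neutrophil granule genes fell in 2 of 10 (median -2.29, camera adjusted p = 7.7e-05, and adjusted p = 0.186 with an estimated correlation), and the haemoglobin list, with 0 of 5 called, had a median of -2.32. The remaining lists did not pass camera. Type I interferon genes rose in 7 and fell in 2 of 27 (median 0.28, adjusted p = 0.72) and interferon gamma genes rose in 6 and fell in 3 of 20 (median 0.76, adjusted p = 0.65). MHC class II rose in 3 and fell in 2 of 10 (median 0.10, adjusted p = 0.84) and hypoxia genes rose in 6 and fell in 5 of 17 (median 0.17, adjusted p = 0.34). Stem genes rose in 3 and fell in 1 of 10 (median 1.02, adjusted p = 0.65), lymphoid genes rose in 2 and fell in 5 of 11 (median 0.30, adjusted p = 0.99), and erythroid or megakaryocyte genes rose in 1 and fell in 1 of 12 (median -0.46, adjusted p = 0.99).

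**Figure D3:**
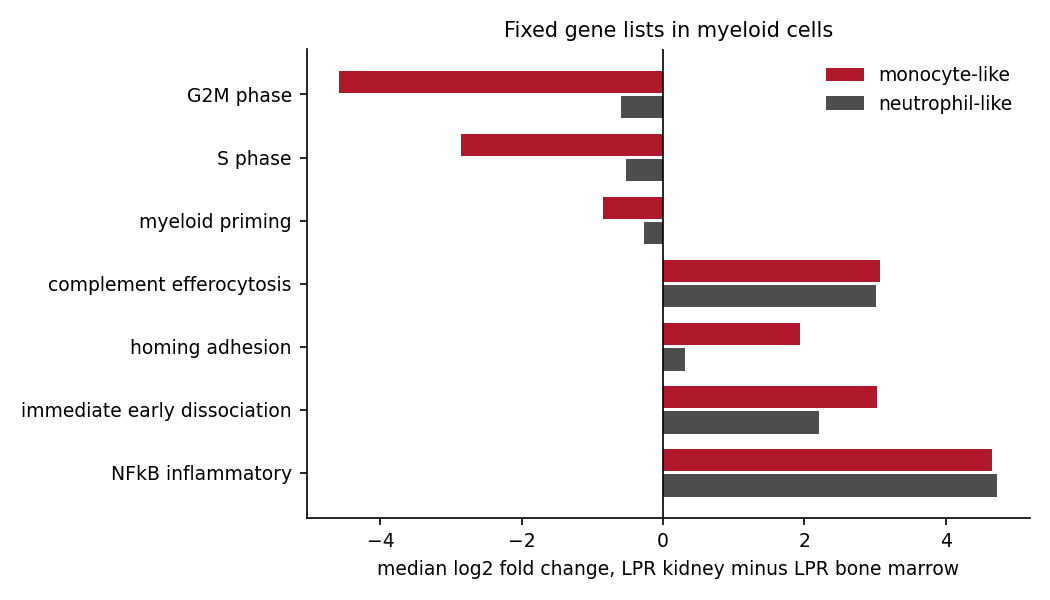
Horizontal bars give the median log2 fold change (x axis) of 7 fixed gene lists, LPR kidney minus LPR marrow, in monocyte-like (red) and neutrophil-like (grey) cells. NF-kB targets stand at 4.65 and 4.72, and the G2M list at -4.58 in monocyte-like cells.

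The patrolling-type cluster alone was then tested, a choice made after seeing the data. Of 8709 genes 451 were higher and 225 lower in kidney (edgeR). With finer clusters, cells with these markers lay apart by tissue. A finer cluster led by Marco held 419, 519, 324 and 149 LPR kidney cells and 3 and 5 LPR marrow cells. One led by Fcgr4 and Adgre4 held 30, 25, 22 and 13 against 116 and 223. The genes named here were not tested within these finer clusters. The chemokine gene Ccl3 rose by 6.49 ± 0.40 (edgeR adjusted p = 9.2e-06), the early response genes Fosb by 6.34 ± 0.70, Nr4a2 by 4.99 ± 0.39 and Egr1 by 4.45 ± 0.79, and Ccl4 was higher by a ratio of 1068 (counting interval 191.6 to 42183). Vcam1, an adhesion molecule, changed by -2.92 ± 0.34 and the complement gene C1qa by -1.38 ± 0.28. Of the NF-kB list 14 of 20 rose (17 adjusted over the list alone, median 2.78, adjusted p = 0.015 with an estimated correlation), and 14 of 18 immediate early genes (18 adjusted over the list alone, median 1.84, adjusted p = 0.011 with an estimated correlation). Ly6a stood at 66.1 CPM in kidney and 56.3 CPM in marrow, a fold change of 0.42 ± 0.54 (edgeR adjusted p = 0.71). The number of changed genes was 121 without LPR marrow replicate 2, 259 without LPR marrow replicate 1 and 440 without LPR kidney replicate 2.

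Neutrophil-like cells of LPR kidney (n = 2, replicates 3 and 4) differed from those of LPR marrow (n = 2) in 895 higher and 902 lower of 6388 genes (edgeR). Cxcl1 (chromosome 5, 90891241 to 90893115, plus strand), a neutrophil attractant, was at least 955-fold higher (edgeR adjusted p = 0.0011), and Il1a, an inflammatory cytokine, at least 482-fold. Ccl3 rose by 10.74 ± 0.67 log2 (edgeR adjusted p = 5.2e-05), Ccl4 by 10.60 ± 0.97, Cxcl3 by 8.92 ± 0.48, Ptgs2 by 8.79 ± 0.54, Cxcl2 by 8.53 ± 0.59 and Hilpda, a lipid droplet protein, by 9.75 ± 0.66. Saa3, an acute phase gene, was 1121-fold higher (counting interval 375 to 5502). It was also a leading gene of a macrophage-like cluster with 790 cells of LPR kidney replicate 3. Whether free RNA enters the Saa3 rise was not tested. Secondary granule genes fell: Camp (chromosome 9, 109847379 to 109849617, minus strand), cathelicidin, by -7.64 ± 0.88 (edgeR adjusted p = 0.001) and Ltf, lactoferrin, by -6.35 ± 0.76 (edgeR adjusted p = 0.0014). Neutrophil-precursor-like cells averaged 21.4% of LPR marrow, and granule genes also fell in kidney T-like cells, as given below. Free granule RNA in marrow may therefore enter these falls. Cybb, the oxidase subunit of the respiratory burst, changed by -3.67 ± 0.49 and Cebpe, a granule gene regulator, by -2.92. Ly6a rose by 2.92 ± 0.37 (edgeR adjusted p = 0.0015). Over all cells Ly6a stood at 952 and 633 CPM in these kidney libraries and at 71.7 and 108 CPM in LPR marrow, so free RNA may enter this rise. Kidney cells lay in a cluster led by Ifitm1, Il1r2, Csf3r, Acod1 and Cxcl2 (161 and 101 cells), while marrow cells lay mostly in 2 others (715 and 1118, and 395 and 1987 cells).

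Among the lists, 20 of 21 NF-kB targets rose (median 4.72, camera adjusted p = 3.3e-30, and adjusted p = 0.323 with an estimated correlation) and 13 of 17 immediate early genes (14 adjusted over the list alone, median 2.21, camera adjusted p = 1.3e-14, and adjusted p = 0.25 with an estimated correlation). Hypoxia and glycolysis genes rose in 8 of 17 (Vegfa, a vessel growth factor, by 3.38; camera adjusted p = 0.0071, and adjusted p = 0.598 with an estimated correlation). MHC class II genes rose in 4 of 5 (H2-Ab1 by 3.35 and Cd74 by 3.40, both of antigen presentation; camera adjusted p = 0.0037, and adjusted p = 0.598 with an estimated correlation). Both genes were also among the 10 leading genes of a kidney macrophage-like cluster, and whether free RNA enters their rise was not tested. Granule genes fell in 6 of 10 (8 adjusted over the list alone, median -3.77, or -2.13 with genes at 0 counts at their bound; camera adjusted p = 8.5e-06, and adjusted p = 0.323 with an estimated correlation). Free granule RNA in marrow may enter this fall too. Tubule genes rose in 6 of 6 (median 10.04, or 8.49 at the bound; Umod at least 257-fold; camera adjusted p = 5.4e-05, and adjusted p = 0.486 with an estimated correlation). Haemoglobin genes fell in 4 of 5 (median -4.99, camera adjusted p = 0.024, and adjusted p = 0.668 with an estimated correlation). No list held with an estimated correlation. Since only kidney was digested, handling and tissue biology cannot be told apart for the NF-kB and immediate early rises. Without LPR marrow replicate 1 or 2 the number of changed genes was 840 or 875 rather than 1797.

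Macrophage-like cells of LPR kidney (n = 4) were set against the 30 such cells of MPJ kidney (n = 1). By edgeR 0 of 13815 genes passed, with 959 at an unadjusted p under 0.05, while DESeq2 called 12 higher and 46 lower. Genes of lipid-laden macrophages had higher mean levels in LPR: Trem2, a lipid receptor, at 539 ± 113 against 71.0 CPM (log2 fold change 2.85 ± 0.43, edgeR adjusted p = 0.47) and Cd9, a tetraspanin, at 361 against 31.5 CPM (3.44 ± 0.70, edgeR adjusted p = 0.49). Apoe, a lipid carrier, was at 1.61 ± 0.39, Ccl3 at -1.25, Egr1 at -1.77 and Ly6c2, a marker of recently arrived monocytes, at -2.76. Ly6a stood at 233 against 78.8 CPM (1.48 ± 0.60, edgeR adjusted p = 0.71). The lipid-associated list had a median of 2.42 with 0 genes called over all genes and 5 adjusted over the list alone (camera adjusted p = 7.8e-12, and adjusted p = 0.305 with an estimated correlation). NF-kB targets had a median of -0.21 with 3 lower adjusted over the list alone (camera adjusted p = 1.3e-05, and adjusted p = 0.305 with an estimated correlation), and type I interferon genes a median of -0.47 (camera adjusted p = 2.9e-05, and adjusted p = 0.950 with an estimated correlation). Tubule genes had a median of -2.50 (Kap, a proximal tubule gene, 3.98 against 331 CPM) and haemoglobin genes of -6.03, so the MPJ cells carried more of both. On simulated data this comparison recovered 0.4% of genes changed 4-fold. Clusters differed too: a cluster led by Gpnmb and Trem2 held 18 of the 30 MPJ cells, against 284 of 519, 1135 of 2569, 999 of 2816 and 374 of 2191 in LPR kidney replicates 1 to 4, and a cluster led by Hspa1a and Il1b held 682 cells of LPR kidney replicate 4 and 0 of MPJ kidney. Monocyte-like and T-like cells could not be compared between strains in kidney, where MPJ held 14 and 9 of them.

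HSPC-like cells of marrow were compared between LPR (n = 2) and MPJ (n = 1), and edgeR called 42 genes higher and 36 lower in LPR of 8520. The fit had 1 residual degree of freedom and assumes that the lone MPJ library varies like the LPR libraries, so it compares these 3 libraries and cannot test the strain. Several myeloid genes had higher levels in the LPR libraries: Elane by 3.16 ± 0.25 (822 ± 3.2 against 90.4 CPM), Ms4a3 by 1.75 ± 0.30, Mpo by 0.75 ± 0.19, and Cpa3, a mast cell protease, by a ratio of 12.6 (counting interval 3.39 to 105). Lower genes included Dntt, the enzyme that adds bases to receptor joints, by -1.78 ± 0.20 (158 against 540 CPM), Notch1 by -1.15, Mef2c by -0.96 and Mki67, a proliferation marker, by -1.30 ± 0.22. HSPC-like cells came from a cluster led by Dntt, Cd34 and Mpo, with 38 of 54 and 35 of 60 LPR cells and 26 of 30 MPJ cells, and a cluster led by Ifitm1 and Meis1. The first of these scored highest on myeloid progenitor markers and second on HSPC markers, and whether the differences hold within a cluster was not tested. Among interferon-inducible genes, Ifi27 was higher in LPR by 2.18 ± 0.35, Bst2 by 1.56 and Iigp1 at least 5.87-fold, while Rsad2 stood at -2.90. Rsad2 was also a leading gene of an erythroid-like cluster. Erythroid-like cells were 33.4% of MPJ and on average 12.8% of LPR marrow, and whether free RNA enters the Rsad2 value was not tested. Of 18 type I interferon genes 2 were called higher and 1 lower (3 and 1 adjusted over the list alone, median 1.02, or 0.79 with genes at 0 counts at their bound, camera adjusted p = 0.0031), and of 14 interferon gamma genes 1 was called higher (3 adjusted over the list alone, median 0.91, camera adjusted p = 3.2e-06). Both had an adjusted p = 0.439 with an estimated correlation. H2-Ab1 and Cd74 were higher by 2.75 ± 0.52 and 1.55 ± 0.33, and Ly6a by 1.80 ± 0.43 (72.3 ± 14.8 against 20.1 CPM). Of 19 myeloid priming genes 6 were called higher and 1 lower (9 and 1 adjusted over the list alone, median 0.98, camera adjusted p = 2.5e-12), of 10 lymphoid genes 5 were called lower (median -0.72, camera adjusted p = 4e-11), and of 7 MHC class II genes 3 were called higher (4 adjusted over the list alone, median 1.25, camera adjusted p = 8.5e-08). Of 51 G2M phase genes 2 were called lower (9 adjusted over the list alone, median -0.55, camera adjusted p = 4.4e-11). With an estimated correlation the myeloid, lymphoid and MHC class II lists had an adjusted p = 0.439 and the G2M list an adjusted p = 0.529. The haemoglobin list had a median of -2.62, with 0 of 5 called, and mt-Nd2, a mitochondrial gene, stood at -1.11. DESeq2 called 1 gene. With finer clusters the class held other cells: the cluster marked by Dntt, Cd34 and Mpo became myeloid-progenitor-like, and a cluster led by Pf4 that scored highest on megakaryocyte markers joined, with 23 and 21 LPR and 25 MPJ cells beside 27, 33 and 10 of the cluster led by Ifitm1 and Meis1. There 18 of the 78 calls were kept, while Mpo stood at -0.36, Mt1 at -0.13 and Tent5c at 0.13.

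Monocyte-like cells of marrow differed between LPR (n = 2) and MPJ (n = 1) in 12 higher and 4 lower of 11566 genes (edgeR). The lone MPJ library is assumed to vary like the other libraries, so the p-values compare these libraries and do not measure the spread between MPJ mice. Fcgr4, an activating Fc receptor, was higher in the LPR libraries by 3.37 ± 0.37 (86.0 against 8.53 CPM, edgeR adjusted p = 0.013), Ms4a3 by 2.11 ± 0.23 (edgeR adjusted p = 0.026), Cfb, complement factor B, by 2.52 ± 0.34 (edgeR adjusted p = 0.026) and Fpr2, a formyl peptide receptor, by 1.60 ± 0.25 (edgeR adjusted p = 0.044). Reep3 (ENSMUSG00000019873, chromosome 10, 67009189 to 67096945, minus strand), an endoplasmic reticulum protein, changed by -2.54 ± 0.24 (12.8 against 76.7 CPM, edgeR adjusted p = 0.0041), Ctla2a, a protease inhibitor, by -2.59 ± 0.39 and Smim5 by -1.41 ± 0.22. Ly6a had a fold change of 2.91 ± 0.92 (edgeR adjusted p = 0.63). Of 16 complement genes 1 was called higher (4 adjusted over the list alone, median 0.68, camera adjusted p = 1.2e-05, and adjusted p = 0.181 with an estimated correlation), and the interferon gamma list had a median of 0.83 (0.77 at the bound, camera adjusted p = 3.3e-06, and adjusted p = 0.462 with an estimated correlation). The Fcgr4-marked cluster held 20 of 793 monocyte-like cells in MPJ marrow against 127 of 1110 and 235 of 1257 in LPR marrow. The number of changed genes was 16, but 4 without LPR marrow replicate 2, 6 without LPR kidney replicate 2, 9 without LPR kidney replicate 4 and 63 without LPR kidney replicate 3, libraries that share the estimate of the spread.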

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

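The comparison here was planned, and no test was chosen after its result was seen. In kidney the macrophage-like share was 21.0 percentage points higher in LPR than in MPJ, and in marrow the same contrast was -0.0358 points, a difference of 21.1 points between tissues. It stood out because every LPR kidney library lay above the MPJ kidney library while both LPR marrow libraries lay below the MPJ marrow library. The marrow side rests on 11 and 16 LPR cells (0.146% and 0.150%) and 11 MPJ cells (0.184%). Its MPJ interval of 0.0919% to 0.329% holds both LPR shares, so the marrow direction is within counting error. Among blood and immune classes alone, macrophage-like cells were 16.5% in MPJ kidney and 21.5% to 43.0% in the LPR kidney libraries. The difference between tissues was not tested, since each MPJ group held 1 library. In groups of 4 libraries, 23 sets of values were also searched for a single library far from the others, and 0 were found.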

How the results depend on the processing

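The equal UMI floor, the gate without haemoglobin genes, the patrolling-type cluster and the other classes were chosen after the data had been seen, and the remaining alternatives were planned. The cause was not tested for any change given here unless stated. With the 3 LPR kidney libraries of one title set summed, exact tests of shares cannot pass, and each gave p = 0.1: HSPC-like -0.640, myeloid-progenitor-like -3.15, monocyte-like -8.76, macrophage-like 22.6 and neutrophil-like -23.1 percentage points between the LPR means, kidney minus marrow, with p over all libraries. Leaving out single libraries likewise raises the smallest p to 0.0571 or 0.0952 by construction, with ranges of -0.717 to -0.564, -3.51 to -2.79, -9.01 to -6.08, 19.2 to 27.5 and -32.2 to -14.1 points in the same order. Among blood and immune classes the monocyte-like difference was -3.15, and under the stricter filter the macrophage-like difference was 24.4. The gate difference of 1.56 points passed with the stricter filter (1.72), with doublets kept (1.74) and unthinned (1.94), and ranged from 1.36 to 1.86 with libraries left out. At 2 or more Ly6a UMIs it was 0.649 and without haemoglobin genes 1.34, with the LPR marrow share at 0.748% rather than 0.278%. Above the equal UMI floor the T-like difference was 6.62 points rather than 21.8, the macrophage-like 32.9 and the neutrophil-like -16.7. The difference in myeloid marker score ranged from -0.291 to -0.259 with libraries left out, where the test cannot pass.

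Numbers of changed genes with a library left out ranged from 3936 (without LPR marrow replicate 1) to 6378 for monocyte-like cells between tissues, from 840 (without LPR marrow replicate 1; 875 without replicate 2) to 1734 for neutrophil-like cells, and from 0 to 1 (without LPR kidney replicate 3) for macrophage-like cells between strains. For marrow monocyte-like cells between strains, main count 16, they ranged from 4 (without LPR marrow replicate 2) through 6 and 9 (without LPR kidney replicate 2 or 4) to 63 (without LPR kidney replicate 3). DESeq2 called 58 genes in macrophage-like cells, 1 in marrow HSPC-like cells and 68 in marrow monocyte-like cells between strains. Without a filter on low counts, macrophage-like cells had 1 call and marrow monocyte-like cells 285. The latter had 41 with the kidney libraries summed and 46 with finer clusters. The title set as a replicate block gave 28 calls there, 5512 and 2005 between tissues in monocyte-like and neutrophil-like cells and 0 in macrophage-like cells between strains. Labels do not say that the set number marks an animal or batch, and the pairing was not used. Among added comparisons between tissues the block gave 75 calls (31 higher, 44 lower) rather than 192 in plasma-like cells, 228 rather than 466 in B-like and 979 rather than 604 in T-like cells. Between strains it gave 15 rather than 23 in proximal-tubule-like, 5 rather than 0 in distal-tubule-like and 0 rather than 2 in endothelial-like cells. Summing gave 272 calls in B-like, 366 in plasma-like and 650 in plasmacytoid-dendritic-like cells between tissues. Without a filter on low counts the numbers between tissues were 1117 in B-like, 937 in T-like, 652 in NK-like, 870 in plasma-like and 1196 rather than 676 in patrolling-type cells. DESeq2 called 244 in NK-like, 536 in dendritic-like and 428 in patrolling-type cells, and finer clusters gave 827 in B-like cells. Of 96 tests of a list in the planned comparisons alone 50 passed camera with the preset correlation, 3 with an estimated correlation and 53 with the libraries summed.

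Directions turned in few cases. Nkg7 in monocyte-like cells between tissues went from -0.74 to 0.60 with doublets kept and 0.66 with finer clusters. In marrow HSPC-like cells finer clusters, which exchanged a cluster of that class for one led by Pf4, put Mt1 at -0.13, Tent5c at 0.13 and Mpo at -0.36, and the megakaryocyte-like share difference at 0. In plasmacytoid-dendritic-like cells between tissues, an added comparison with 1 kidney library, summing put Vcam1 at 2.18 and C1qc at 3.73. Among single genes and added comparisons, 9624 other values under settings that keep every library stayed on their side of the threshold, 370 newly passed and 335 no longer passed. With a library left out the numbers were 5303, 142 and 537. RLE scaling moved no planned split between higher and lower calls by over 10 points.

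The block and single-library fits of marrow HSPC-like cells, and the stricter filter and the minimum of 50 cells for macrophage-like cells, were not run because too few cells or libraries were left. Alternatives of the planned comparisons that had too few cells on 1 side were not run either. No count model compared groups of 3 or more libraries on each side, so other splits were not counted for them, while shares have their exact permutation tests. The macrophage-like and HSPC-like comparisons between strains rested on 30 MPJ cells each.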

Other observations

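Of the tests here, the free RNA test of immediate early genes, the free Ly6a test and both Reep3 tests were chosen only after the result was seen, as were all comparisons of further classes. T-like cells of LPR kidney differed from those of LPR marrow in 398 higher and 206 lower of 11454 genes (edgeR, n = 4 and 2). Among the genes higher in kidney were Rgs1, which restrains chemokine signalling, by 4.43 ± 0.34 log2 (1110 against 60.5 CPM), Gzmb, a cytotoxic granule protease, by 3.02 ± 0.35 (edgeR adjusted p = 0.0026), Ifng by 2.84 ± 0.36 (edgeR adjusted p = 0.0044) and Nr4a1, induced by receptor signalling, by 6.08 ± 0.46. Gzmm, a granzyme, changed by -3.25 ± 0.19. The class lay in unlike clusters: one led by Gzmb and Cd8a held 131, 745, 670 and 412 kidney and 5 and 13 marrow cells, and one led by Cd8b1 with Gzmm and Tcf7 held 9 to 56 kidney and 47 and 175 marrow cells, and Gzmb and Gzmm were not tested within a cluster. Of 18 exhaustion and effector genes 5 rose (8 adjusted over the list alone, median 1.35, camera adjusted p = 0.025 with an estimated correlation), and of 18 immediate early genes 11 (18 alone, median 2.53, adjusted p = 0.018 with an estimated correlation). Granule genes fell in 7 of 10 (median -6.38) and tubule genes had a median of 9.20, or 4.79 at the bound. The number of changed genes was 61 without LPR marrow replicate 2, 304 without LPR marrow replicate 1 and 347 without LPR kidney replicate 2. NK-like cells also rose in Gzmb (3.77 ± 0.48, edgeR adjusted p = 0.004), Rgs1 (4.65 ± 0.37) and Ifng (2.60 ± 0.34), with Tcf7, a factor of less mature cells, at -2.98 ± 0.31. Dendritic-like cells rose in H2-Eb1 (2.44 ± 0.21) and H2-Aa (1.71 ± 0.15), which present antigen, and in 8 of 10 MHC class II genes (median 1.70, adjusted p = 0.124 with an estimated correlation). Ccl17, a T cell attractant, was at least 55.8-fold higher in them, while 26 of 39 S phase genes fell (median -1.83, adjusted p = 0.124 with an estimated correlation). NK-like cells had 278 higher and 122 lower genes (168 changed without either LPR marrow replicate 1 or 2), and dendritic-like cells 584 and 348 (471 and 275 changed without LPR marrow replicate 1 or 2). B-like cells had 279 and 187 (308 changed without LPR kidney replicate 3, 232 without LPR marrow replicate 2) and plasma-like cells 115 and 77 (322 and 118 changed without LPR kidney replicate 1 or 2, 60 without LPR marrow replicate 2). Plasmacytoid-dendritic-like cells, with 1 kidney library assumed to vary like the marrow libraries, had 262 and 95 by edgeR, 51 and 8 by DESeq2, and 468 and 182 with the kidney libraries of one title set summed.

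Between strains in kidney, proximal-tubule-like cells had 3 genes higher and 20 lower in LPR of 13511 (edgeR), against 152 and 190 by DESeq2, 59 and 108 with the libraries of one title set summed, 37 and 116 with finer clusters, 9 and 51 under the stricter cell filter and 60 and 121 without a filter on low counts. The lone MPJ library, of which 76.9% of barcodes failed the mitochondrial filter, is assumed to vary like the LPR libraries, so these calls compare libraries and do not test the strain. The class also lay in unlike clusters: one led by Kap and Aadat held 472 of 1780 MPJ cells and 82, 136, 68 and 168 cells of LPR kidney replicates 1 to 4, and another led by Akr1c21 and Miox held 88 MPJ cells and 1722, 158, 49 and 102 LPR cells. A further one led by Miox and Acaa1b held 636 MPJ and 1375, 119, 24 and 163 LPR cells. C4b, a complement component with a near-identical copy in C4a, was higher in the LPR libraries by 3.41 ± 0.43 (80.0 against 5.74 CPM, edgeR adjusted p = 0.039). Lower genes included Hdc, which makes histamine, by -5.30 ± 0.27 (edgeR adjusted p = 0.00051), Hpgd, which breaks down prostaglandins, by -4.32 ± 0.41 (edgeR adjusted p = 0.013), Acadm, of fatty acid oxidation, by -2.15 and Acox2 by -2.54. MHC class II genes had a median of 2.87 and interferon gamma genes of 3.16, with 0 of 9 and 0 of 20 called over all genes, 8 and 12 adjusted over the list alone, and an adjusted p = 0.635 with an estimated correlation for each. Without LPR kidney replicate 1 this class had 2558 changed genes, and without replicates 2, 3 or 4 it had 12, 14 and 14. Dendritic-like cells had 13 genes lower in LPR, 8 of them mitochondrial transcripts such as mt-Co1 (-2.32 ± 0.22), and the MPJ kidney library kept a median of 14.6% mitochondrial counts. They had 8 higher and 15 lower by DESeq2, 12 and 21 with the libraries summed, 17 and 38 without a filter on low counts and 25 and 36 where at least 50 cells were required. Endothelial-like cells had 2 lower genes, Reep3 (-2.98 ± 0.22, edgeR adjusted p = 0.045) and Hpgd (-2.46 ± 0.20, edgeR adjusted p = 0.049), but 1264 without LPR kidney replicate 1 and 0 without each other kidney replicate, with the title set as a block, or with the libraries of one set summed. By contrast DESeq2 called 99 higher and 21 lower, and 43 and 15 passed without a filter on low counts. With finer clusters these cells lay apart by strain. A cluster led by Plvap and Flt1 held 4 MPJ cells and 101, 132, 140 and 474 LPR cells. An unnamed one led by Tm4sf1 held 33 MPJ cells and 48, 54, 81 and 78 LPR cells. Distal-tubule-like cells had 0 changed genes of 13265 by edgeR, with 1692 at an unadjusted p under 0.05, 279 by DESeq2, 246 without a filter on low counts, 63 with the libraries summed and 259 without LPR kidney replicate 1.

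Immediate early genes were higher in kidney than in marrow in monocyte-like cells. A difference between the title sets was excluded as the whole source, since the median log2 difference was 3.09 within one set and 3.47 within the other. Tissue or its preparation remains open and had support: in dendritic-like cells the list was higher by 3.92 in MPJ kidney than in MPJ marrow, against 2.86 in LPR. With finer clusters that class held 6 rather than 29 MPJ marrow cells, so unlike makeup may enter the value. Free RNA from other kidney cells could not be excluded, because in 1 LPR kidney library the median ratio of the level in monocyte-like cells to that over all cells was 0.966, and 2.01 in the highest. Since only kidney was digested, handling and tissue biology cannot be told apart, and the rise may come from either. The same limit holds for the NF-kB targets and chemokine genes that rose in kidney monocyte-like, patrolling-type and neutrophil-like cells.

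Reep3 was lower in LPR than in MPJ across classes: the MPJ library lay above every LPR library in 19 of 19 pairs of class and tissue, 5 in kidney and 14 in marrow, with a median ratio of 3.77 (range 1.81 to 7.78). It was one of 9 genes, among 4561 scanned, with the same sign in all pairs and a median over 1 on the log2 scale. The others included Hbb-bt, Hba-a2 and mt-Atp8, lower in LPR, and Tsc22d3, Per1 and Ighg3, higher, while 51 genes had 1 sign in all pairs, so haemoglobin and mitochondrial RNA and other properties of whole libraries give the same pattern. A difference between the title sets was excluded, since within the set that holds both MPJ libraries the median log2 ratio was -1.78 and the highest -0.85. A candidate explanation is a strain difference at or near this gene, but with 1 MPJ library per tissue it cannot be told apart from a property of those animals or libraries.

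Macrophage-like cells averaged 54.7% of the thinned kidney gate, but 38.5% unthinned and 47.2% at 2 or more Ly6a UMIs. Of all thinned macrophage-like cells of LPR kidney 4.36% lay in the gate, so the size of the class also sets its part. Free Ly6a RNA could not be excluded: the level in macrophage-like cells was 2.50 to 12.1 times that in NK-like cells of the same library, with a lowest counting bound of 1.15. Doublets with endothelial cells, which carry abundant Ly6a, also stay open: pooled, gate cells held 1.03 times the endothelial marker UMIs of other macrophage-like cells, though 1 library reached 4.05 times. Expression of Ly6a by kidney macrophages may therefore account for the gate's makeup only as a hypothesis.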
